A study of Mus musculus with 81 samples.

How the data were processed

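Cells came from pancreata of wild-type CD1 mouse embryos at embryonic day 13.5 that were dissociated with trypsin, per the labels' protocols. Single cells were captured on a microfluidic device, amplified with SMARTer chemistry (full-length cDNA by template switching) and made into Nextera XT libraries, per the labels' protocols. Each of the 81 libraries carries a pair of index sequences and was read in 2 lanes, per the labels. The submitters' processing notes name CASAVA 1.8.2 and the genome build mm9. The aligner, the counting tool, the annotation release and any filter on cells are not given in the sources used here.

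The deposited table holds 1 value per transcript and cell for 29510 transcript rows of 22869 gene symbols, with mm9 coordinates that count from 1. The unit is not stated in the table. It was taken as RPKM, made by the authors, because the deposited values times transcript length fall on multiples of 1 read. Lengths came from GENCODE vM21 (GRCm38), which was used for lengths, names and transcript sequences and never for coordinates. The median over cells of the share of low values within 0.15 of a whole number of reads was 83.5%, and the lowest was 79.4%. The worth of 1 read gave the estimated reads per cell. In the shallow cells C3, C61, C94 and C43, 1 read in a transcript of 1 kb is worth 50.7, 13.9, 5.09 and 2.38 RPKM. This is above the detection threshold, so a value of 0 in these cells limits little and a detection in them can rest on 1 read.

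A gene was represented by its transcript row of highest mean, since isoforms share reads. Some transcripts that every cell uses were near 0: Gapdh averaged 0.622 RPKM and was above 0 in 57 of 81 cells, and Rps2 averaged 1.14 RPKM, while Actb averaged 4289 RPKM. Of the 50-base windows of the longest Gapdh transcript 82.5% occur in transcripts of other genes, and of Rps2 71.3%. Genes at 0 are therefore called listed at 0. A total of 9029 transcript rows were 0 in every cell. Mitochondrially encoded genes were not analysed here.

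All 81 cells passed a filter of 1000 genes above 0. Genes above 0 in at least 3 cells (13237) were put on the log2(RPKM + 1) scale. Genes of the readout lists and a seeded random 50% of the remaining genes outside the marker lists were held out. From the rest, 1000 genes of high variance for their mean gave 10 principal components and 10 Ward clusters. A cluster took the name of the marker list of which the largest share reached 10 RPKM in at least 50% of its cells, with at least 3 markers. A cluster with a median of estimated reads under 1/3 of the median of all cells and no marker among its 10 leading genes stayed unnamed. These rules for naming a cluster, including the level of 10 RPKM, were set after the values had been seen. Only the markers had been fixed before. No doublet caller was run, as 81 cells are too few for one. Instead, 15 cells with at least 3 markers at 10 RPKM of both an epithelial-type list and the mesenchyme list were counted. The mesenchyme list includes Vim, at 10 RPKM in 80 of 81 cells, and Isl1, which is also on the endocrine list.

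The labels name no animals, so the cells are 1 sample and no p-value was computed. Class means, SDs over cells and differences are descriptions. For 23 readout lists with measured genes, the median difference was placed among 10000 random lists of held-out genes, matched on level in 20 bins. A list outside the central 95% of these is named higher or lower, and members at least 1 log2 unit apart are counted. A difference on this scale understates the change of low genes. Genes named are the 12 held-out genes of largest difference in each direction that are above 0 in at least 50% of the cells of the higher class, of which the text gives a part; up to 4 genes per list outside the range; fixed genes of the detection analysis, of which the text gives a part; and the fixed markers with the highest mean in a class. C91, C45, C13, C20 and the transcripts named with them, the cell pair C82 and C77, and the other markers given cell by cell in the closing section were chosen after their values were seen. The lists, markers, thresholds of detection and cycling, comparisons and most alternatives were fixed before the data were examined.

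Shares have exact Clopper-Pearson intervals at the 95% level and a share of 0 has a limit of 3 counts; both cover counting error only. Reads without molecular identifiers are not independent molecules. Each first index belongs to 1 of 12 plate columns and each second index to 1 of 8 plate rows, so a shared index and a shared plate position are the same thing here.

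The list method and clustering were tested on simulated data built from the 2 largest clusters, the lists with 6 cells against 61 and 12516 genes and the clustering with 67 cells and 14081 genes. Of 50 genes changed by each fold, 66% were higher at 2-fold, 94% at 4-fold, 86% at 8-fold and 98% at 16-fold. Any difference above 0 counted as higher. The share of unchanged genes above 0 was not counted, so these shares are not rates of detection. A list of 30 genes changed 8-fold lay at percentile 100. Of 300 unchanged lists 15 fell outside the range, and 11 did with 200 changed genes among those drawn from. This part of the test was enlarged after a first version, with fewer lists and only upward changes in the genes drawn from, had put more of them outside the range than chance would. A group of 4 cells with 60 private genes formed its own cluster of 4. Simulated values were drawn separately for each gene, so the genes of a list did not vary together within a cell. The test thus does not show how often an unchanged list of genes that vary together falls outside the range. The endocrine comparison of 2 against 4 cells was not simulated. Alternatives covered the cell filter, variable genes, components, clusters, Leiden clustering, rescaling each cell to the same total, pseudocounts, a filter on low values, the detection threshold, the 2 ranges of cell numbers and naming cells one by one. Work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.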

Results

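Pancreatic cells of wild-type CD1 mouse embryos at embryonic day 13.5 were profiled one cell per library, on a microfluidic device that captures single cells and makes cDNA from each. The file held RPKM values (reads scaled by transcript length and by the mapped reads of the library) for 81 cells. The labels give 1 group and name no animal, so the 81 cells were treated as 1 sample. No test was made between classes of cells, and every SD below is a spread over cells. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. The RPKM values fall on steps of 1 read, which gave an estimated median of 3.53M reads per cell. In 77 cells the estimate was at least 1.66M reads, and the highest was 5.37M. The other 4 cells (C3, C61, C94 and C43) had an estimated 19.7K, 72.2K, 196.6K and 419.3K reads. Between 2353 and 6311 genes per cell reached 1 RPKM, with a median of 4057.

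The first question was which cell types the dissociated pancreas contained. Mesenchymal-like cells, in which the collagen genes Col1a2 and Col3a1 had higher class means than in any other named class, made up 67 of the 81 cells (82.7%, 95% interval 72.7% to 90.2%). Epithelial-like cells were 4 of 81 (4.94%, 1.36% to 12.2%) and carried Epcam, Cdh1, Krt8 and Cldn6. Another 2 cells, C24 and C56 (2.47%, 0.3004% to 8.64%), were endocrine-like. Leukocyte-like cells, with the macrophage transcripts Tyrobp, Fcer1g, C1qb and Laptm5, were 4 of 81 (4.94%). A cluster of 3 cells (3.70%, 0.770% to 10.4%) was endothelial-like, although Emcn, Egfl7, Pecam1 and Cdh5 each reached 1 RPKM in only 2 of them, C22 and C72. The third, C20, had none of these 4 genes at 1 RPKM, and no endothelial-like cluster formed under 10 of the 15 alternative settings. Cell C3, the shallowest, formed a cluster of its own and was left unnamed. The other shares also changed with the method. Leiden clustering named 100% of cells mesenchymal-like. It linked each cell to more neighbours than any small class has cells, so it could hardly set one apart. Naming each cell by its highest-scoring marker list gave 30.9% mesenchymal-like and 14.8% epithelial-like cells. It also named 5 cells erythroid, 7 gut and 9 mesothelial. Those scores were taken against the mean over all 81 cells, which pulls a class of most cells toward 0 on its own markers.

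Within the mesenchymal-like class, Col1a2 averaged 173.4 ± 102.4 RPKM (SD over 67 cells) and Col3a1 127.4 ± 84.9 RPKM. The intermediate filament gene Vim did not set the class apart, with a median of 541.3 RPKM against 521.9 RPKM in the 4 epithelial-like cells. Rgs5, a pericyte gene, reached 1 RPKM in 59 of the 67 cells, while the smooth muscle actin gene Acta2 did so in 19. Wt1, a transcription factor gene of mesothelium and visceral mesenchyme, reached 1 RPKM in 48 cells and Tcf21, a regulator of visceral mesenchyme, in 48. The class joins 5 clusters of 30, 24, 6, 4 and 3 cells. In these, 6, 6, 7, 5 and 7 of the 21 measured mesenchyme markers, which include Vim, reached the naming level. The shares were larger in the other named clusters: 7 of 12 pan-epithelial, 19 of 26 endocrine, 12 of 14 leukocyte and 8 of 14 endothelial markers. The mesenchymal-like name thus rests on a smaller part of its list than the others do. Mesenchymal-like cells were 77.5% (61.6% to 89.2%) of the 40 cells numbered 1 to 48 and 87.8% (73.8% to 95.9%) of the 41 cells numbered 49 to 96.

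**Figure D1:**
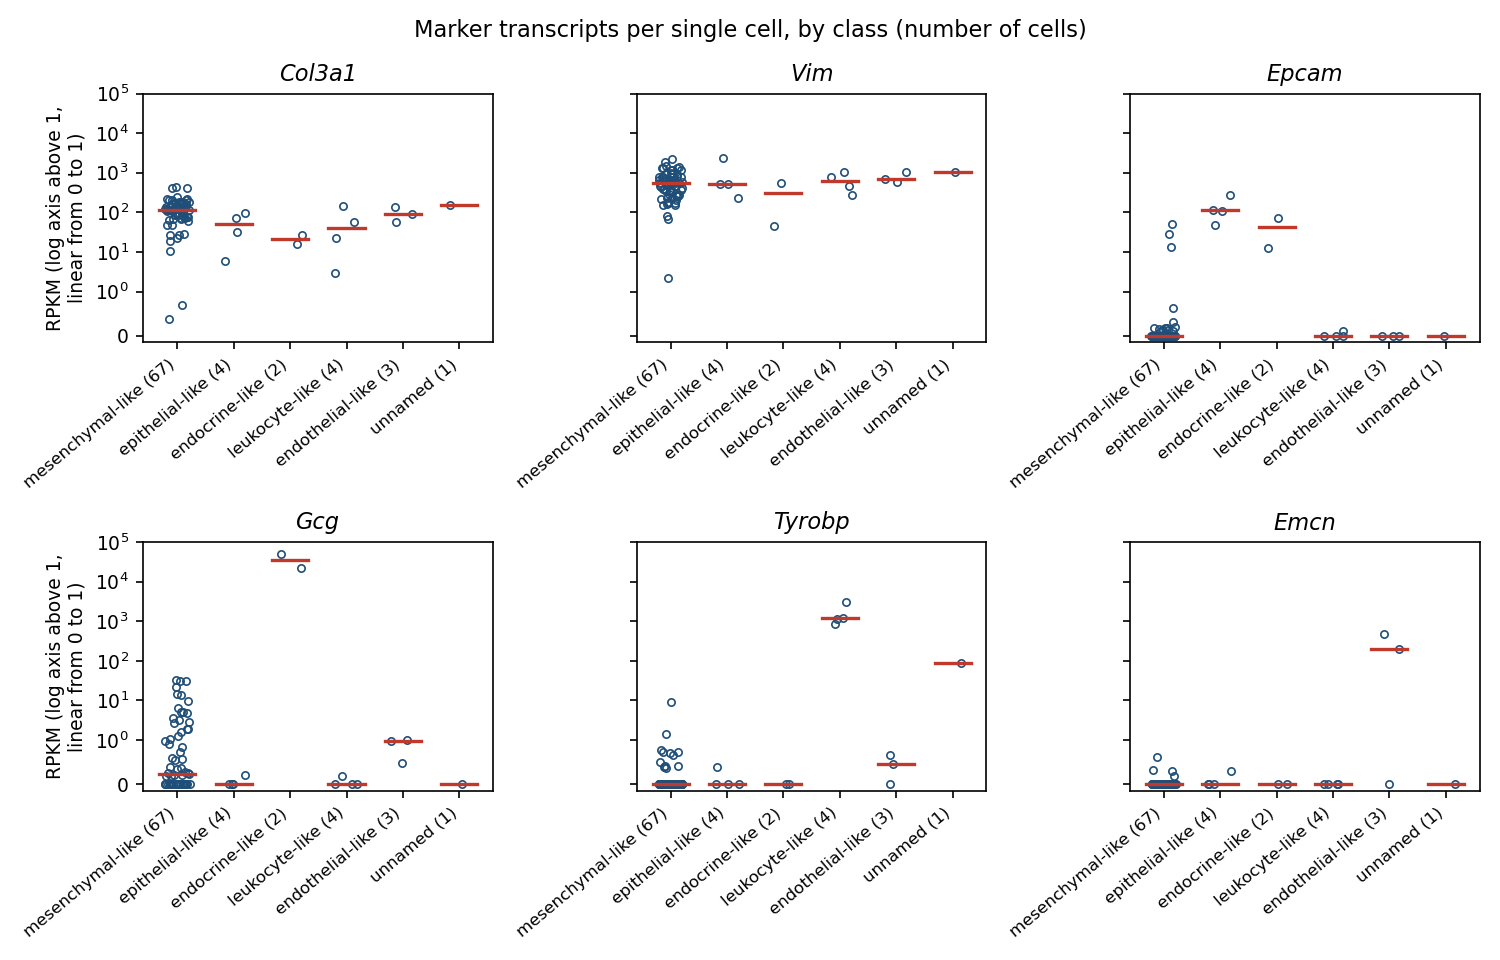
RPKM of 6 marker genes in each of the 81 cells, on an axis that is logarithmic above 1 and linear from 0 to 1. Each circle is 1 cell, red lines are class medians, and numbers in brackets are cells per class. Gcg reached 48650 and 22610 RPKM in the 2 endocrine-like cells, while Vim was at 1 RPKM or more in all 81 cells.

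The second question was how many cells carried each regulator of the pancreatic lineages, taking 1 RPKM as detection. Sox9, a progenitor factor gene (chromosome 11, 112643524 to 112649071, mm9), was detected in 29 of 81 cells (35.8%, 25.5% to 47.2%). These were the 4 epithelial-like cells, with 86.2, 200.5, 306.7 and 53.7 RPKM in C43, C47, C82 and C95, together with 22 mesenchymal-like cells and 3 others. Pdx1, the regulator of pancreatic identity (chromosome 5, 148081707 to 148086725), was detected in C43 alone, at 86.9 RPKM (1.23%, 0.0313% to 6.69%). C43 is also one of the 4 shallow cells. It carried Sox9 and Nkx6-1, the latter at 49.1 RPKM, as well.

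Nkx6-1 was detected in 5 cells (6.17%, 2.03% to 13.8%), which were the 4 epithelial-like cells and C91, and all 5 also had Sox9. Ptf1a, a regulator of acinar fate, was listed at 0 in all 81 cells, which limits detection in the file to 3.70% of cells and leaves open how many cells hold the transcript. Cpa1, a digestive carboxypeptidase gene of tip and acinar cells (chromosome 6, 30589221 to 30595361), was detected in 12 cells (14.8%, 7.90% to 24.5%), 11 of them mesenchymal-like. Its highest value, 803.6 RPKM, was in the epithelial-like cell C82. Since no cluster was tip-like, tip and trunk cells were not compared.

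Neurog3, the gene of the factor that starts endocrine differentiation (chromosome 10, 61595838 to 61597511), was detected in 1 cell, C91, at 258.0 RPKM. C91 was classed as mesenchymal-like, so it counts on the mesenchymal side below and is not part of the endocrine comparison. Chga, a granin of secretory granules, was detected in C24 and C56, at 107.3 and 40.7 RPKM. Ins1 was detected in C56 at 31.8 RPKM and Ins2 in no cell. Gcg, which encodes proglucagon (chromosome 2, 62312587 to 62321710), reached 1 RPKM in 23 cells (28.4%, 18.9% to 39.5%), including 20 mesenchymal-like cells and 1 endothelial-like cell. The 21 cells with Gcg outside the endocrine-like class all shared a library index with C24 or C56, and none of the 51 cells that shared no index with them reached 1 RPKM. Among the 12 cells sharing only the first index the median was 8.21 RPKM, and among the 15 sharing only the second it was 1.02 RPKM. Detection of Gcg outside C24 and C56 was therefore not read as expression in those cells. Cpa1 was above 0 in 15 of 30 cells that shared an index with C82 or C77, the pair with the highest values, and in 5 of the 49 that shared none. At 1 RPKM the counts were 5 of 30 and 5 of 49, with up to 36.9 RPKM (C42) among cells sharing none. At that threshold a shared index set the cells apart far less for Cpa1 than for Gcg.

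**Figure D2:**
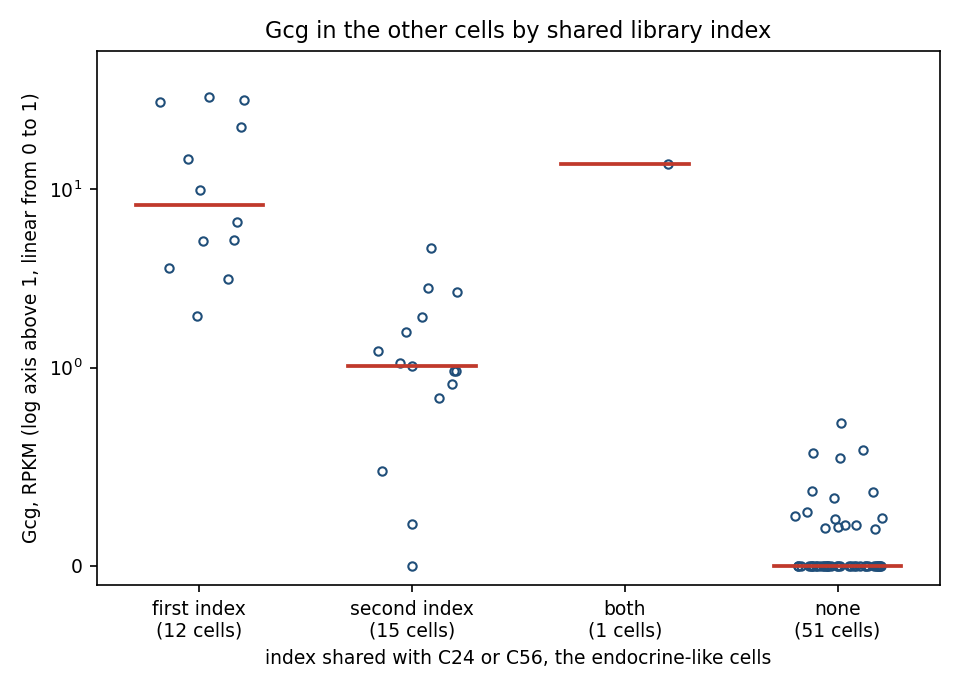
Gcg in RPKM (logarithmic above 1, linear from 0 to 1) in the 79 cells other than C24 and C56, by the library index each shared with either of them. Circles are cells and red lines medians. All 12 cells sharing the first index lie above 1 RPKM, and the highest of the 51 cells sharing none is 0.718 RPKM.

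The third question was what sets the epithelium apart from the mesenchyme around it. The 4 epithelial-like and 2 endocrine-like cells were compared with the 67 mesenchymal-like cells, using genes kept out of the clustering. The epithelial side had more transcript of genes for oxidative phosphorylation and cell junctions. The mesenchymal side had more of the factors that drive epithelial to mesenchymal transition, extracellular matrix and imprinted genes. Differences in vesicle exocytosis and immediate early genes were outside the random range only with the 2 endocrine-like cells included. Of 23 lists, the median difference of 3 lay above and of 6 below the central 95% of 10000 random lists of equal size and level. Differences are in log2(RPKM + 1).

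Among factors of epithelial to mesenchymal transition, 4 of 6 measured genes were lower in the epithelial group by at least 1 (median of the list −1.57, percentile 0.01). Zeb2 reached 1 RPKM in 55 of the 67 mesenchymal-like cells and 1 of the 6 others, with a difference of −2.84. Snai2 differed by −2.83, although C24 and C47 held 79.4 and 77.3 RPKM of it. Of 39 extracellular matrix genes, 12 were lower and 5 higher by at least 1 (median −0.26, percentile 0.01). The metalloproteinase inhibitor gene Timp3 averaged 4.94 ± 2.40 in mesenchymal-like cells and 1.98 ± 2.60 in the 6 epithelial and endocrine-like cells. The basement membrane gene Nid1 differed by −2.37, and Col18a1, another basement membrane gene, was 2.09 higher on the epithelial side.

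Imprinted genes had a median of −0.62 (percentile 0), with 6 of 19 lower and 2 higher by at least 1. Plagl1, a zinc finger factor gene, averaged 7.16 ± 1.95 in mesenchymal-like cells against 4.25 ± 3.48, and was at 296.4 and 279.7 RPKM in C47 and C95. Igf2, a fetal growth factor gene, averaged 6.29 ± 1.44 against 4.43 ± 2.90, and Peg3 went the other way, with a difference of 1.76 that turned to −0.16 when each cell was named by its highest-scoring marker list. Immediate early genes had a median of −0.29 (percentile 0.07, and 2.84 without C24 and C56), and 5 of 20 were lower and 0 higher by at least 1. Klf4 was detected in 45 of 67 mesenchymal-like cells and 2 of 6 others, and Zfp36 in 43 and 1. In the Hedgehog list (median −0.54, percentile 0.37) 6 of 8 genes differed by less than 1. The co-receptor gene Gas1 differed by −1.97, and Smo, the signal transducer, was 2.02 higher on the epithelial side. Integrins lay just outside the random range (median −0.14, percentile 2.12), with Itga8 at −2.08, and kept that place in 2 of 11 alternatives.

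On the epithelial side, 18 of 27 oxidative phosphorylation genes were higher by at least 1 and 0 lower (median 1.35, percentile 99.7). Uqcrc1, of respiratory complex III, averaged 6.39 ± 1.23 against 3.78 ± 2.85. Uqcrfs1, Cox5a and Sdha were each detected in all 6 cells and in 44, 35 and 43 of the 67 mesenchymal-like cells. When the share of cells with each gene detected was compared instead of the level, the list lay inside the random range (percentile 90.8). Vesicle exocytosis genes had a median of 0.82 (percentile 100) with 10 of 27 higher by at least 1, but without C24 and C56 the list lay at percentile 74.6, inside the random range. The exocytosis list was also inside that range when each cell was named by its highest-scoring marker list. Resp18, Aplp1 and Abcc8 of that list were listed at 0 in the 4 epithelial-like cells. Vamp8, a vesicle fusion gene, was at 178.4 to 332.0 RPKM in those 4 cells. Of 16 cell junction genes 7 were higher by at least 1 (median 0.71, percentile 98.4). The claudin genes Cldn3 and Cldn7 and the splicing regulator gene Esrp1 were each detected in 4 of 6 epithelial and endocrine-like cells and 0 of 67 mesenchymal-like cells.

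Among the held-out genes outside the lists, the largest differences toward the epithelium were in Bex1 (7.16), Wfdc15b (5.51), Atp1b1 (5.04), Spint2 (4.84) and Arl3 (4.82). Bex1 was detected in all 6 cells and in 15 of 67 mesenchymal-like cells. Wfdc15b, and the kinesin gene Kif12, were each detected in 5 and in 0. Toward the mesenchyme they were in Sulf2 (−3.57), a heparan sulfate sulfatase gene, Nrk (−3.28), Mcc (−2.92), Parp8 (−2.86) and Gsn (−2.78), which encodes the actin regulator gelsolin. Nfib, a transcription factor gene, was detected in all 67 mesenchymal-like cells and averaged 6.28 ± 0.94 against 3.54 ± 1.92. Myl9 was listed at 0 in all 6 epithelial and endocrine-like cells. Epithelial-like cells also had more reads (median 4.57M against 3.52M) and more genes at 1 RPKM (4760 against 4032). All 6 cells of the epithelial side also held at least 3 mesenchymal markers at 10 RPKM. These markers include Vim, which reached 10 RPKM in 80 of the 81 cells. Of 11 alternatives, 10 kept the call for oxidative phosphorylation, 9 that for cell junctions and 8 that for Hedgehog genes, which ended without C24 and C56.

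**Figure D3:**
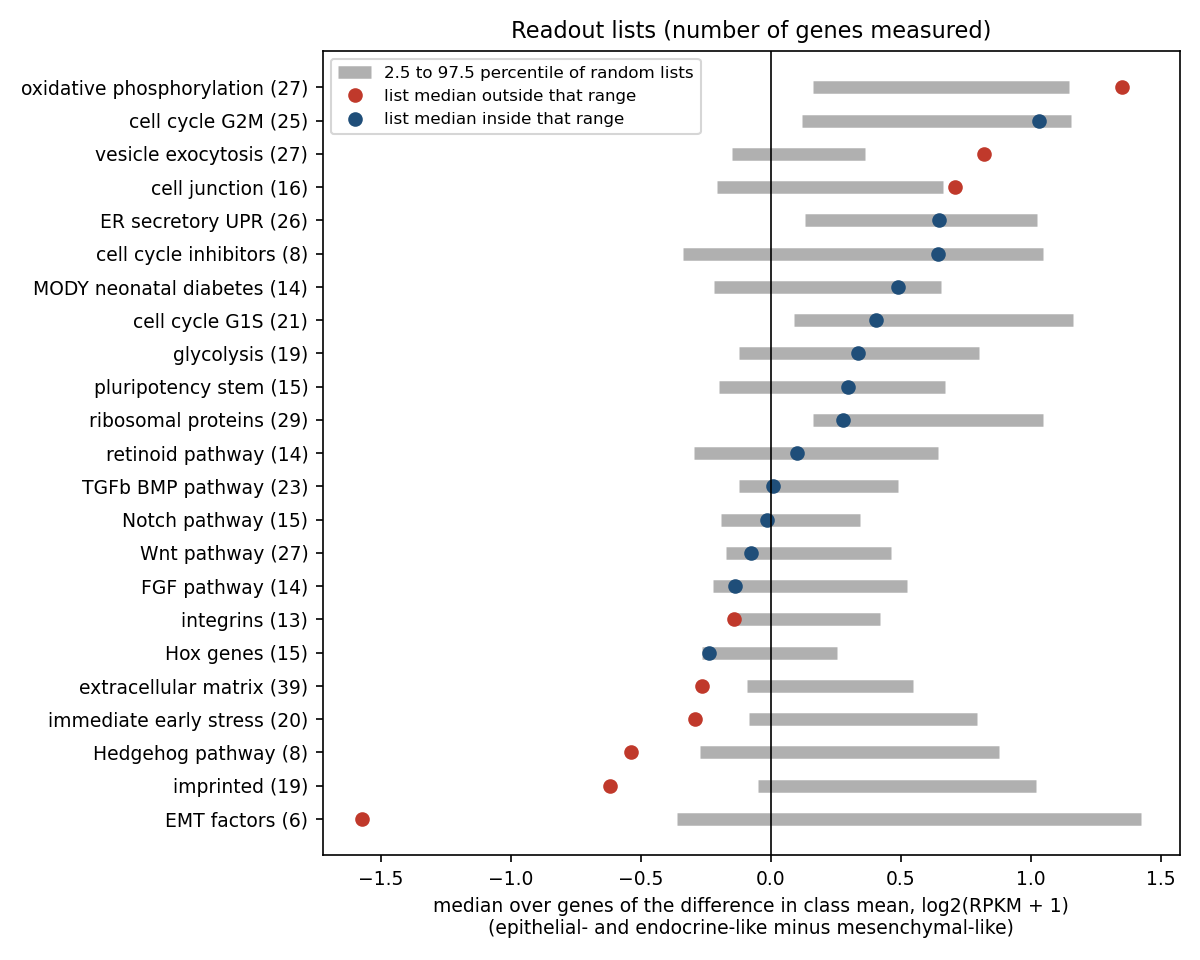
Median difference in class mean, in log2(RPKM + 1), for 23 gene lists between the 6 epithelial and endocrine-like cells and the 67 mesenchymal-like cells, with the number of measured genes in brackets. Grey bars span the central 95% of 10000 random lists and red points lie outside them. Oxidative phosphorylation is at 1.35 and factors of epithelial to mesenchymal transition at −1.57.

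The fourth question was what distinguishes endocrine cells from the other epithelial cells. C24 and C56 held transcripts of hormones and of a hormone carrier at very high level: Gcg at 48650 and 22610 RPKM, Pyy at 7814 and 10390, and Ttr, the carrier gene, at 7518 and 6259. Among genes kept out of the clustering, Tmem27, which encodes collectrin, was at 2852 and 1739 RPKM in C24 and C56 and listed at 0 in all 4 epithelial-like cells. The hormone gene Sct (355.1 and 878.0 RPKM) and the neuropeptide gene Gal (142.1 and 421.4 RPKM) were also listed at 0 in those 4 cells. With 2 cells against 4, each statement describes these cells only, and a value of 0 in the shallow cell C43 limits little.

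Vesicle exocytosis genes were higher in the endocrine-like cells (median difference 1.62, percentile 100), with 14 of 27 higher and 2 lower by at least 1. Resp18, a secretory granule gene, was at 279.0 and 306.5 RPKM, Aplp1 at 146.0 and 99.7, Syt13 at 129.0 and 20.4, and Abcc8, the sulfonylurea receptor gene, at 56.7 and 39.3, and all 4 were listed at 0 in the epithelial-like cells. Genes of the G2/M phase of the cell cycle were lower (median −2.04, percentile 0), with 17 of 25 lower and 3 higher by at least 1. Nusap1 was at 0.304 and 0 RPKM in C24 and C56 against 64.1, 39.5, 18.2 and 125.8 in C43, C47, C82 and C95, and Ube2c at 9.62 and 4.94 against 7.34 to 384.8. Ribosomal protein genes were lower (median −1.02, percentile 0.195), 16 of 29 by at least 1. For these a median of 47.4% of the 50-base windows of each transcript is shared with transcripts of other genes, so their levels are uncertain. Rplp0 was at 66.5 and 81.4 RPKM in C24 and C56 against 268.7 to 1397 in the others.

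The Hox list was also lower (percentile 1.72), but Hoxa5 and Hoxa2 were each detected in 1 epithelial-like cell only, and Hoxb3 was higher in C24 and C56 (21.6 and 3.21 RPKM). That call was kept in 5 of 8 alternatives, and the exocytosis and ribosomal calls in 7 of 8. Among other genes, Commd3 was listed at 0 in C24 and C56 and lay between 122.3 and 189.1 RPKM in the epithelial-like cells. Zyx, a focal adhesion gene, was at 1.43 and 0 RPKM against 37.1 to 132.6.

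The last question was in which classes proliferation transcripts were found. At least 5 of 25 G2/M genes reached 10 RPKM in 52 of 81 cells (64.2%, 52.8% to 74.6%). This held for 39 of 67 mesenchymal-like cells (58.2%, 45.5% to 70.2%), for all 4 epithelial-like cells (39.8% to 100%), for all 3 cells of the endothelial-like cluster and for 3 of 4 leukocyte-like cells. The unnamed shallow cell C3 also passed, but 1 read in a transcript of 1 kb is worth 50.7 RPKM there. A gene can thus reach 10 RPKM in C3 on 1 read. The same limit applies in the mesenchymal-like cell C61, where such a read is worth 13.9 RPKM. Both endocrine-like cells passed as well, with 8 and 9 genes, against a median of 15 in the epithelial-like and 8 in the mesenchymal-like cells. Between the epithelial and mesenchymal sides, 14 of 25 G2/M genes were higher and 1 lower by at least 1 on the epithelial side. The list median there lay inside the random range (percentile 93.75) with C24 and C56 included. Without those endocrine-like cells it lay above that range. The intervals of the epithelial- and mesenchymal-like shares overlap.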

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

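The settings that average a gene's transcripts, leave out the 4 shallow cells, leave out C91 and C45 with or without C13, leave the endocrine-like cells out of the epithelial side, change the naming level to 5 or 20 RPKM, or compare with the plate row and column were chosen after seeing the data. The cause of the changes below was not tested. The 2 cell filters removed no cell, so they test nothing and are left out of the counts below. The comparisons without cells holding both epithelial and mesenchymal markers were not run, because all 6 epithelial and endocrine-like cells hold both, and no tip-like class existed to vary.

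Of 75 class shares under other settings, 58 stayed inside the interval of the reported share. That interval covers counting error only and is wide for small classes. A change from 4 to 8 epithelial-like cells, for example, stays inside it. The endothelial-like share was 0 with fewer variable genes, pseudocount 0.1, 5 or 20 components, 6 clusters, Leiden clustering, all genes, rescaling, averaged transcripts or without the shallow cells. Leiden clustering put 100% of cells in mesenchymal-like clusters and 0 in epithelial-, endocrine- and leukocyte-like ones. With more neighbours per cell than these classes have cells, it could hardly set them apart. Rescaling each cell to the same total gave 0 endocrine-like cells and 8 epithelial-like ones. Naming each cell by its highest-scoring list gave 30.9% mesenchymal-like and 14.8% epithelial-like cells. Its scores, taken against the mean over all cells, work against a class of most cells.

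In the epithelial and mesenchymal comparison the numbers of lists above and below the random range stayed within 1.5 times the reported ones, except that 3 lists were lower without the endocrine-like cells. That setting ended the exocytosis, immediate early, Hedgehog and integrin calls, put the G2/M list above the range, and turned Resp18 (−0.0213), Aplp1 (−0.38) and Abcc8 (−0.0163), as these are 0 in the other 4 cells. Lists of transition factors, matrix and imprinted genes kept their call in all 11. Of the genes named, Phb2 (−0.0247), Tmem98 (0.39) and Peg3 (−0.16) turned direction when each cell was named by its highest-scoring list. That naming set 14 cells against 25. Naming by the highest-scoring list also ended the exocytosis, Hedgehog and integrin calls. In the endocrine comparison that setting gave 6 lower lists and turned Commd3 (0.12), Cog4 (0.0598), 9430023L20Rik (0.21) and Rpl26 (0.28). A pseudocount of 10 gave 5 lower lists, and a mean of at least 5 RPKM left 0 higher ones. The G2/M call was kept in all 8 alternatives.

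Detection depended on the threshold. Above 0, Sox9 was in 59.3% of cells, Cpa1 in 27.2%, Gcg in 55.6% and Col3a1 in 100%. At 5 RPKM, Sox9 was in 24.7% and Gcg in 14.8%. After rescaling, Gcg was in 50.6% and Col3a1 in 100%. Cells 1 to 48 had 0 with Neurog3 or Ins1, and cells 49 to 96 had 0 with Pdx1 and 100% with Col3a1. Without the shallow cells 0 had Pdx1. Asking a value to exceed a small fixed fraction of the highest in the same plate row or column left Gcg in 2.47% of cells. With 3 G2/M genes as the limit, 75.3% of all cells and 71.6% of mesenchymal-like cells passed.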

Other observations

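The tests on Gcg between libraries and on the sex of the libraries were chosen after the values had been seen, and those on collagen before, except that the cells C45 and C13 were set beside them afterwards. The 4 leukocyte-like cells, C2, C31, C36 and C54, carried macrophage genes. Tyrobp was at 1240, 3019, 866.5 and 1131 RPKM in them, the fractalkine receptor gene Cx3cr1 at 62.9, 388.6, 50.03 and 244.2, and the growth factor receptor gene Csf1r at 96.1, 378.9, 102.0 and 44.9. Pf4 varied most, at 3094 RPKM in C31 and 1065 in C36 against 15.3 in C54 and listed at 0 in C2. In the endothelial-like cluster, C22 and C72 held Emcn at 468.4 and 193.5 RPKM and Kdr, a vascular growth factor receptor gene, at 72.2 and 21.8.

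Some cells grouped with the mesenchymal-like class carried genes of other cell types. C91 held Neurog3 at 258.0 RPKM with Rfx6 at 173.8, Nkx2-2 at 68.6, Pax4 at 18.6 and Cdkn1a at 71.4, all genes of endocrine progenitors, and Epcam at 27.6. C45 held the neural crest genes Sox10 at 31.9 RPKM and Fabp7 at 731.6, and its Col1a2 was 0.269 RPKM. C13 held the epithelial genes Epcam at 51.6 RPKM and Krt8 at 131.3, but Cdh1 and Cldn6 were listed at 0 in it, Col3a1 was at 0.367 RPKM and Col1a2 at 37.8. The endocrine-like cell C24 also held Gast at 257.1 RPKM and Th at 55.6, both listed at 0 in C56, while Ins1 and Apoa1 (40.99 RPKM) were present in C56 and listed at 0 in C24. Fgb, a gene of liver cells, was at 130.7 and 266.7 RPKM in C24 and C56.

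Gcg in libraries that share an index with C24 or C56 may come from reads passed between libraries. Gcg was above 0 in 27 of the 28 libraries sharing an index and in 16 of 51 sharing none, a ratio of shares of 3.07. Free RNA in the suspension, or low expression in other cells, would not depend on the index, yet the median in libraries sharing the first index was 11.4 times the highest value among those sharing none. The origin of the low values in the 16 libraries that share no index stays open. An index and a plate row or column go together, so handling on the plate and index errors cannot be separated, and no other biological explanation was tested.

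Collagen transcripts were present in the 13 leukocyte-, endothelial-, epithelial- and endocrine-like cells, with a median of 43.8 RPKM of Col1a2 against 162.2 in mesenchymal-like cells. The 13 include C20, which had no Emcn, Egfl7, Pecam1 or Cdh5 at 1 RPKM and held Col1a2 at 64.9 and Col3a1 at 136.8 RPKM. Reads passed at the rate seen for Gcg would give a median of 0.296 RPKM, and the observed median was 148.1 times that, at least 142.1 times with any 1 cell left out, which argues against that route. For free mesenchymal RNA the planned test decides nothing: the 10th percentile of the carried share over 586 transcripts abundant in mesenchymal-like cells was 1.68 times the share of Col1a2 (33.4%), but many of these are made by every cell. Outside the 13 cells, Col3a1 was at 0.691 RPKM in C45 and 0.367 RPKM in C13, and Col1a2 at 0.269 and 37.8 RPKM, so collagen was far below that share of the mesenchymal level in both for Col3a1 and in C45 for Col1a2, though these few cells do not exclude free RNA in the others. For 2 cells in 1 capture site the planned test, Xist beside Y-linked transcripts, found 0% of the 13 cells, but no library had Xist at 10 RPKM, so this too stays open, as does low collagen expression by the cells themselves, which was not tested.

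No library had Xist, the X inactivation transcript of female cells, at 10 RPKM; the highest value was 4.14 RPKM, in the shallow cell C3. A Y-linked gene (Ddx3y, Eif2s3y, Kdm5d or Uty) reached 1 RPKM in 80 of 81 libraries (98.8%), and all 81 had one above 0. This is consistent with libraries from male embryos only. The number of embryos is not given in the sources used here.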
